A study of Drosophila melanogaster with 2 samples.

How the data were processed

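The data are anti-GFP ChIP-seq peak lists from whole Drosophila melanogaster embryos aged 0 to 24 h that express a CG31224-eGFP fusion, with 2 biological replicates in 1 group, as the labels give them. Per the labels' protocols chromatin was sonicated to fragments of 200 to 800 bp. The deposited files are 8 peak lists: for each replicate and for both replicates together a ranked list and a list past an IDR threshold, with a conservative version of each series-level list. Per the deposited description files the lists use the dm6 genome and derive from the alignments of the replicates and a control alignment, and the thresholded lists derive also from a further file that the ranked lists do not derive from. The control was not analysed here. The aligner, the peak caller and their versions are not given in the sources used here.

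Each deposited peak has an interval, a summit, a signal value and an IDR score. The signal value is a score that the authors' peak caller gave to the peak; its scale is not given in the sources used here, it grows with the pool (the median ratio of the main list's value to the sum of the 2 replicates' values is 1), and it was used only to rank, filter and describe peaks and to compare the replicates over the same peaks. The deposited IDR score is 830 or more in every thresholded list, which stands for an IDR of at most 1%, and the deposited ranked lists hold the −log10 of the IDR, which was not used in any test. Read counts were not analysed here, so depth per sample is unknown, and confidence intervals cover only the counting of peaks or genes. Peaks and genes are not replicates of the experiment: p-values over them describe these 2 libraries.

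The series-level thresholded list that is not the conservative one was the main list, and each replicate's own list gave the check of replicate error. Peaks on 2L, 2R, 3L, 3R, 4, X and Y were kept, and 5 peaks of the main list on unplaced scaffolds were left out. Genes and TSSs came from Ensembl release 115 (BDGP6.54) and sequence from the RefSeq copy of the same assembly as dm6. Entries for single mature microRNAs, 481 in number, were left out of the genes after the data were seen, because their 5' ends are not TSSs; keeping them left the promoter share at 47.8%. Coordinates are 1-based.

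The tests, the 30 gene lists, the 31 sequence elements, the rule for named genes and most alternative settings were fixed before the data were examined. The rule named CG31224, the 20 peaks with the highest signal with the gene of the nearest TSS (a coding one first where it lay within 500 bp), up to 4 bound members per gene list (8 for patterning genes), and the 5 strongest peaks found in a single replicate's list. Of 530 symbols listed by name, 27 were not in the annotation; 14 lists were defined by symbol patterns, and the pattern for histone genes also takes in variant histones.

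Overlap between replicates needed 1 bp and was compared with 1000 random placements on the same chromosomes. Summit positions were classed by distance to the nearest TSS (500 bp) and then by 5' UTR, coding exon, 3' UTR, non-coding exon, intron and intergenic DNA, again against 1000 random sets. A gene counted as bound with a summit within 500 bp of any of its TSSs; lists were tested by two-sided Fisher's exact test with intervals from the log odds with 0.5 added to each cell, against all other protein-coding genes, or against all genes for the RNA lists. Elements and 6-mers were counted within 50 bp of the summit and in windows of that width centred 300 bp to each side, with an exact sign test against the flank on a random side. Median signals were compared by 100000 permutations. All adjusted values are Benjamini-Hochberg, at a threshold of 0.05.

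For the closing section a motif was learned after the main results were seen. From the 150 strongest peaks over 500 bp from a TSS on 2L, 2R and X, and separately on 3L and 3R, the 8-mer with the largest excess over the flanks was extended and refined into a weight matrix, in up to 10 rounds. A match is a score above that of 95% of the flanks used in learning. Other word lengths and a motif learned from promoter peaks were looked at before this one was chosen and are not reported. Peaks were always scored with the matrix from the other arms.

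Each step was tested on simulated peaks on the real genome. With no effect planted, 16 of 300 simulated promoter shares, 15 of 300 differences of median signal and 4 of 60 paired-promoter shares had a p below 0.05, and 0 of 270 gene-list tests, 0 of 310 element tests and 0 of 20800 6-mer tests had an adjusted p below it. When 45% of the genes of lists of 40 or more were bound, 297 of 300 such lists were found. Chromosome tests gave 0 of 70. First runs with fewer draws had missed planted gene lists and had given more promoter shares below 0.05 than that threshold allows; the number of draws was raised after those outcomes were seen, and those tests were left as they were. A planted sequence was learned and found in all 549 summits that held it on arms not used, and in 76 of 804 that did not. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

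The alternatives were the conservative list, the peaks above the median signal, each replicate's own list, TSS distances of 250 and 1000 bp, a local random placement, peak midpoints, a single TSS per gene, other windows and flanks, summits away from TSSs, and stricter or looser overlap. Added after the data were seen were leaving out summits within 300 bp of a stronger one, using all ranked peaks with a score of 830 or more, assigning each summit to 1 gene, coding TSSs alone or distance-matched TSSs for paired promoters, keeping mature microRNA entries, and setting replicates against each other's ranked lists or correlating them over all main-list peaks.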

Results

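Chromatin immunoprecipitation followed by sequencing (ChIP-seq) with an antibody against GFP was carried out on whole Drosophila melanogaster embryos collected 0 to 24 h after laying. The embryos came from transgenic flies carrying CG31224 fused to eGFP, and the peaks mark DNA recovered with the antibody. The series holds 1 group of 2 biological replicates, and the deposited measurements are peak lists in dm6 coordinates. The main list, made from both replicates, held 3815 peaks past a 1% irreproducible discovery rate (IDR), of which 3810 lay on the 7 chromosomes analysed (2L, 2R, 3L, 3R, 4, X and Y). A conservative version held 3697 peaks, and the lists of replicate 1 and replicate 2 alone held 2405 and 2604. Peaks of the main list were 336 bp wide at the median, and their signal values, the authors' own score per peak on a scale that no source used here states, ran from 2.04 to 4550 with a median of 89.0. Read depth is unknown. The design has no second group, so every comparison below is between positions, genes or replicates.

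The first question was whether the gene whose product was tagged carried a peak itself. CG31224 (FBgn0051224, 3R:18650121-18659309, minus strand) had a peak at its own promoter, at 3R:18659266-18659601, with the summit 125 bp upstream of the transcription start site (TSS). Its signal value was 278 in the main list, rank 369 of 3810, with 154 in replicate 1 and 130 in replicate 2. A second, weaker peak at 3R:18663458-18663793, 4317 bp upstream of the TSS, had a signal value of 58.5. This upstream peak was also in the list of replicate 2, at 37.7, but in neither the list of replicate 1 nor the conservative list. Whether the transgene carries DNA of this locus was not examined, and reads from such DNA would map here too.

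**Figure D1:**
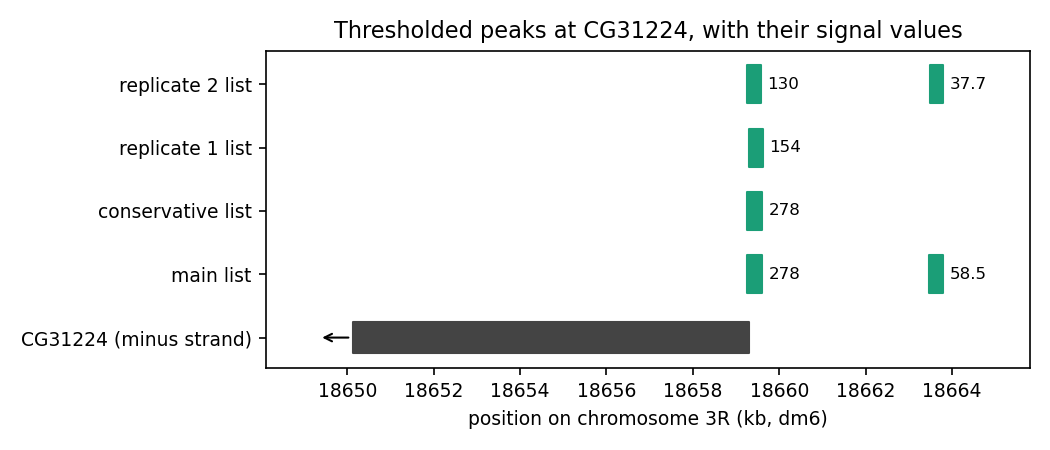
Map of CG31224 on chromosome 3R (horizontal axis, position in kb, dm6), with thresholded peaks of each list as green boxes labelled with their signal value. The promoter peak is in all 4 lists, at 278 in the main and conservative lists, 154 in replicate 1 and 130 in replicate 2, and the upstream peak in the main list (58.5) and the list of replicate 2 (37.7).

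Several genes held more than 1 of the strongest peaks. The strongest of all, 2L:12497585-12497975, had a signal value of 4550 (2446 in replicate 1 and 2126 in replicate 2) and lay 446 bp upstream of t-cup, inside the gene bunched (bun). The next was at 2R:14006750-14007210, with a value of 4304, in an intron of mastermind (mam), which encodes a coactivator of Notch signalling, 948 bp from mir-4978. A further peak in a mam intron, 2R:14008305-14008693, reached 2671. Tousled-like kinase (Tlk) held 3 of the 20 strongest peaks, at X:3777256-3777695 (3732, 114 bp downstream of the annotated start of mir-4962), X:3740801-3741326 (2774) and X:3742050-3742964 (2494). CG9331 was the nearest gene to 3 of the 20, between 2L:20821702 and 2L:20824141, with values of 1741, 2135 and 2539. The SUMO-conjugating enzyme gene lesswright (lwr) carried its peak in the 3' UTR, at 2L:540582-541177, with a value of 3044.

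These ranks are within the main list, which lacks 6 of the 20 highest peaks of the longer ranked list. All of the 6 but the peak near ssp3 (2018) lie in a single region, 2L:12002955-12012662. In that region 2 peaks near Rh5 have higher values than any peak kept. Long non-coding RNA genes were nearest to 4 of the 20 strongest peaks. These were lncRNA:CR45297 (3736), lncRNA:CR44867 (2526, inside beat-Ib), lncRNA:CR44366 (2106) and lncRNA:CR45352 (1992). The other named neighbours were CG10365 (2833, in an intron), alpha-Est8 (2570), tRNA:Ala-TGC-2-1 (1876), CG14100 (1808), Ugalt (1797) and tRNA:Phe-GAA-1-7 (1790, 6117 bp away). Among the 100 strongest peaks 43% lay within 500 bp of a TSS, against 58.8% of the next 400 and 43.7% of those ranked 2001 to 3810.

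The only sample-to-sample comparison in the design is between the replicates. Of the 2402 chromosomal peaks of replicate 1, 1861 (77.5%, 95% Wilson interval 75.8 to 79.1) overlapped a peak of replicate 2 by at least 1 bp, and 1852 of 2602 peaks of replicate 2 (71.2%, 69.4 to 72.9) overlapped replicate 1. Random placement on the same chromosomes gave 1.15% and 1.04% (one-sided permutation p = 0.001 for each, the smallest that 1000 placements can give). Across the 1861 shared peaks, which are not independent replicates, signal values correlated with Spearman's rho = 0.790 and, on the log2 scale, Pearson's r = 0.81. The log2 ratio of replicate 1 to replicate 2 had a median of -0.08 and an SD of 0.66. Main-list peaks overlapping both had a median signal of 149 (1863 peaks), against 57.8 for the 839 peaks that overlapped neither.

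The 5 strongest peaks past the threshold in a single replicate lay near CG10311 (3R:16356241-16356484, 247), lncRNA:CR45640 (192), lncRNA:CR45293 (167) and by (123) in replicate 1, and near drongo (119) in replicate 2. All 5 were in the main list, but those near CG10311, lncRNA:CR45640 and by had no summit within 100 bp in the longer ranked list of replicate 2. Of the 541 peaks found only in the list of replicate 1, 441 had a summit within 100 bp in the ranked list of replicate 2, and 611 of the 750 found only in replicate 2 had one in that of replicate 1.

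**Figure D2:**
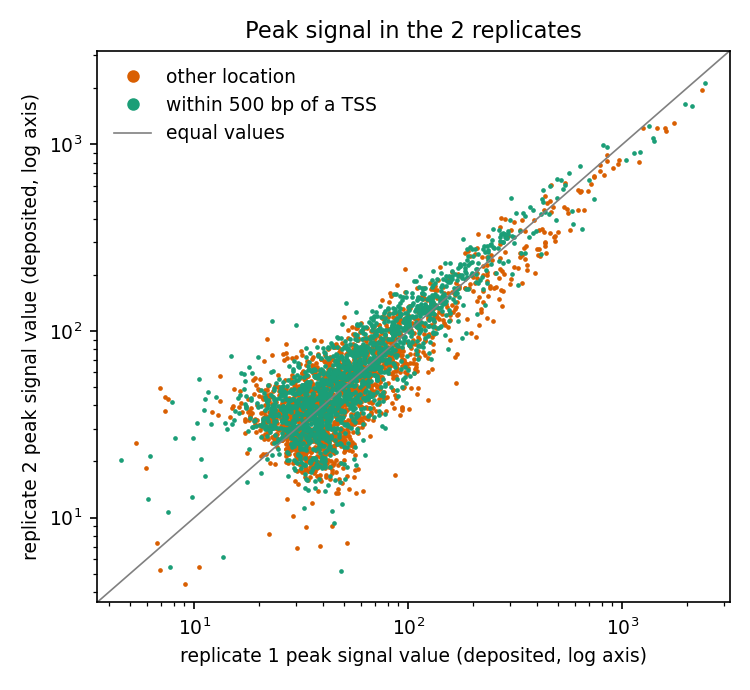
Signal value of each main-list peak in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis), deposited units, for the 3493 peaks with a summit within 100 bp in both ranked lists; green points lie within 500 bp of a TSS, orange points elsewhere, and the line marks equal values. Values in the replicates rise together (rho = 0.759).

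Peak summits were concentrated at promoters and nearly absent from coding exons. Within 500 bp of an annotated TSS lay 1823 of 3810 summits (47.8%), 3.52 times the 13.6% ± 0.538 (SD) of random positions on the same chromosomes. Coding exons held 32 summits (0.84% against 13.7% at random) and 3' UTRs 43 (1.13% against 4.42%). Introns held 35.6% of summits against 39.4%, and intergenic DNA 13.1% against 27.3%. Each of these 5 differences had a two-sided permutation p = 0.001, the smallest possible. The classes exclude each other and promoters were assigned first, so the high promoter share lowers the other shares by construction. The lower intron and intergenic shares therefore do not by themselves show avoidance. Introns held 1355 of the 1987 summits outside promoters, and intergenic DNA 500. That is a larger part for introns, and a smaller part for intergenic DNA, than of the random positions outside promoters. These parts were not tested. The share in 5' UTRs beyond 500 bp of a TSS was 0.446% against 0.785% (permutation p = 0.028), and that in non-coding exons was 1.05% against 0.812% (permutation p = 0.0929). The promoter share was 49.6% in the list of replicate 1 and 52.3% in that of replicate 2. Against positions moved by only 10 to 50 kb, which keeps the local gene density, random sets had 17.2% at promoters, and the observed share was 2.79 times that. No ChIP of embryos without the fusion was analysed here, so these shares include any recovery of promoter DNA that does not need the tagged protein.

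**Figure D3:**
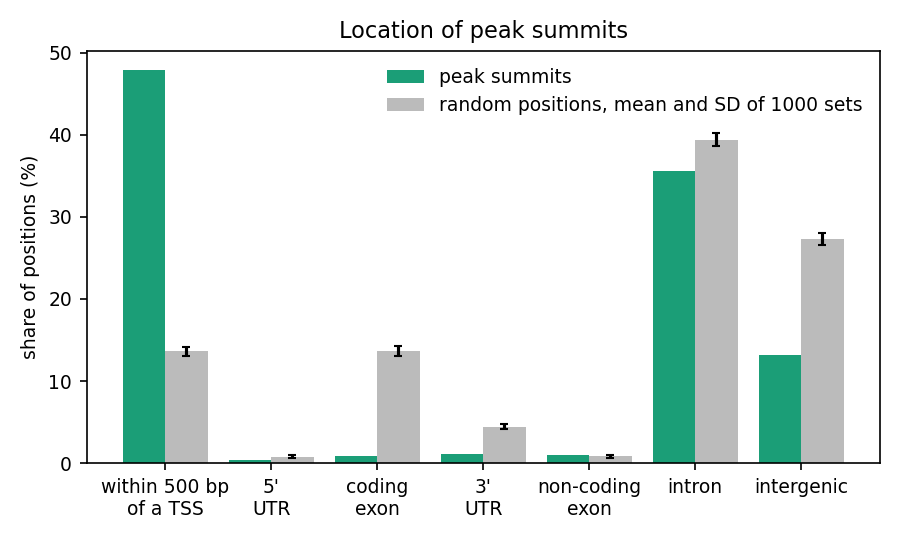
Share of peak summits (green, n = 3810) and of random positions on the same chromosomes (grey, mean with SD of 1000 sets) in each annotation class, in percent. Promoters hold 47.8% of summits against 13.6% of random positions, and coding exons 0.84% against 13.7%.

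Promoter summits sat just upstream of the start site. Their median position was 104 bp upstream of the nearest TSS, with quartiles at -185 and -17 bp, and 1427 of 1823 (78.3%) lay upstream. Promoter peaks had higher signal values than other peaks, with medians of 96.7 and 84.3, a difference of 12.4 (two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). The difference was 4.70 in replicate 1 (permutation p = 0.0164) and 3.88 in replicate 2 (permutation p = 0.0213), on signal scales that are lower than that of the pooled list.

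Promoter summits often lay near start sites on both strands. TSSs on opposite strands both lay within 500 bp of 654 of the 1823 promoter summits (35.9%), against 12.2% ± 0.752 (SD) of random positions near TSSs (permutation p = 0.001, the smallest possible). Random TSSs given each summit's own distance and side had 26.1% ± 1.01, so that the excess over this comparison was 1.37-fold (permutation p = 0.001). This matched comparison was added after the first result was seen.

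Chromosome 4 was nearly free of peaks. It held 2 peaks where its length predicts 37.0 (adjusted exact p = 3.11e-13, two-sided exact binomial test with Benjamini-Hochberg adjustment over 7 chromosomes), and 28.1 were predicted from its number of coding TSSs (adjusted exact p = 3.59e-09). The ratio to the number predicted from length was 0.054, against 0.171 in the list of replicate 1 and 0.198 in that of replicate 2. The Y chromosome had none, against 94.8 predicted from length (adjusted exact p = 3.22e-41), and 4.55 from its TSSs (adjusted exact p = 0.0427). Chromosome arm 2L held 731 peaks, 1.12 times the number predicted from length (adjusted exact p = 0.00235), but 1.02 times that predicted from TSSs (adjusted exact p = 0.548). Arm 3L held 1.08 times the number that its TSSs predict (adjusted exact p = 0.0427). With promoter peaks alone, given the number of TSSs, only chromosome 4 passed, with 1 peak against 13.4 (adjusted exact p = 0.000325). Predictions from length count every known base. How much of each chromosome can be read uniquely, and its copy number in these embryos, were not measured. The low counts on the Y and on chromosome 4 therefore need not mean that the protein avoids them.

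Genes for cytoplasmic ribosomal proteins had the highest bound share of the 30 lists. A gene was called bound where a summit lay within 500 bp of a TSS, as it did for 55 of 85 such genes (64.7%), against 15.2% of other protein-coding genes, an odds ratio of 10.2 (95% interval 6.50 to 15.8, adjusted exact p = 3.48e-23, two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 30 lists). In the lists of replicate 1 and replicate 2, 44 and 48 of these genes were bound, with odds ratios of 9.41 and 9.46. RpL7 (2L:10200914-10201135, signal 352, summit 42 bp from a TSS), RpS27 (345), RpL34b (296) and RpL32 (272) had the highest signal values among them. Mitochondrial ribosomal protein genes were bound in 20 of 73 cases, with an odds ratio of 2.06 (1.26 to 3.49, adjusted exact p = 0.0326). Their strongest members, mRpL41 (1392), mRpS10 (1160), mRpS23 (917) and mRpL23 (827), had higher signal values than any cytoplasmic member. This second call held under only 3 of 10 alternative settings. The adjusted p was 0.302 in the list of replicate 1, 0.0633 in that of replicate 2, and 0.688 with each summit given to a single gene.

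Cuticle, chemoreceptor, digestive protease and histone genes were bound less often than other genes. Of 142 cuticle and tracheal genes 6 were bound (odds ratio 0.238, adjusted exact p = 0.000172), among them Cht11 (138), Cht7 (123), Osi24 (67.3) and Cpr47Ec (55.4). Each replicate's own list had 2 of the 142 bound, with odds ratios of 0.121 and 0.101, and Osi24 and Cpr47Ec in neither. Of 231 chemoreceptor and odorant-binding protein genes 2 were bound, Obp99b (103) and Obp83g (79.7), with an odds ratio of 0.0467 (adjusted exact p = 1.9e-13). None of 31 digestive protease genes was bound (95% interval of the odds ratio 0.00527 to 1.41, adjusted exact p = 0.0348), a call that held under 5 of 10 alternatives and in the list of neither replicate. Of the genes matched by the histone pattern 1.74% were bound, His2Av (87.4) and His3.3B (63.4), which encode replication-independent variants (odds ratio 0.0955, adjusted exact p = 9.79e-06). Of the 3810 main-list peaks, 4 had most of their 31 bp stretches more than once in the assembly. Whether peaks could be called at histone genes that occur in several copies was not tested, so their low share need not mean absence of the protein. Over the 10 alternatives the odds ratio ran from 0 to 0.0974 for chemoreceptor genes, 0 to 0.15 for histone genes and 0.101 to 0.346 for cuticle genes, with each call kept. The lists of replicate 1 and replicate 2 gave 0.0364 and 0.0304 for chemoreceptor genes, and 0.15 and 0 for histone genes.

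Transfer RNA genes, microRNA genes and the joint list of small nuclear and nucleolar RNA genes were also bound less often than other genes. For microRNA and small nucleolar RNA genes the TSS used was the annotated 5' end of the entry, which need not be where transcription starts. Their low shares therefore may not measure binding at promoters. Transfer RNA genes were bound in 9 of 295 cases (odds ratio 0.205, adjusted exact p = 2.22e-08), led by tRNA:Ala-TGC-2-1 (1876) and tRNA:Tyr-GTA-1-8 (290). MicroRNA genes were bound in 6 of 260 cases (odds ratio 0.154, adjusted exact p = 8.61e-09), with mir-4962 (3732), mir-4978 (687), mir-9377 (175) and mir-275 (140) the highest. Small nuclear and nucleolar RNA genes were bound in 22 of 306 cases (odds ratio 0.507, adjusted exact p = 0.00484), with snoRNA:Psi28S-2949 (216) the highest. By annotated type the low share was that of nucleolar RNA genes, 15 of 269 (5.58%), while small nuclear RNA genes had 6 of 32 (18.8%), against 13.2% of all genes; the types were not tested apart. In the lists of replicate 1 and replicate 2, 9 and 11 of the 306 were bound, with odds ratios of 0.305 and 0.317. The joint call was lost at a TSS distance of 1000 bp, where the odds ratio was 1.09 (adjusted exact p = 0.772). Over the 10 alternatives the odds ratio ran from 0.18 to 0.478 for transfer RNA genes (0.354 in the list of replicate 1) and 0.101 to 0.293 for microRNA genes, with each call kept.

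Lists of regulators of chromatin and of replication did not pass the threshold. The Polycomb and Trithorax group had 10 of 31 genes bound (adjusted exact p = 0.0624), with brm (691), ph-p (595), E(z) (334) and Psc (79.6) the highest. Insulator and architectural proteins had 8 of 25 (adjusted exact p = 0.0969), led by Chro (925), Cp190 (374), Trl (212) and BEAF-32 (149). DNA replication genes had 12 of 43 (adjusted exact p = 0.091), led by Dp (274), RnrS (193), chif (131) and Mcm2 (119). The Polycomb and Trithorax list passed at a TSS distance of 250 bp (adjusted exact p = 0.0351) and with a single TSS per gene (0.0225), and the insulator list there (0.0314) and in the list of replicate 2 (0.0307). The Polycomb and Trithorax odds ratio of 2.60 fell to 1.27 in the list of replicate 1 (adjusted exact p = 0.825) and 1.05 among peaks above the median signal (0.941), and the DNA replication odds ratio of 2.11 to 1.39 in the list of replicate 1 (0.751). C2H2 zinc finger regulators had 8 of 31 (odds ratio 1.90, adjusted exact p = 0.264), with CG31224 itself the highest, followed by D19B (151), M1BP (93.9) and lola (87.8). The lists of replicate 1 and replicate 2 had 3 and 6 of the 31 bound, with odds ratios of 0.914 and 1.71.

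Lists of developmental regulators did not differ from other genes past the threshold. Of 8 Hox genes 2 were bound, Dfd (71.1) and Antp (62.3), adjusted exact p = 0.513. Of 35 segmentation genes 3 were bound, bowl (244), nkd (133) and ptc (49.6), adjusted exact p = 0.513. Of 31 dorsoventral patterning genes 2 were bound, cact (185) and ush (51.2), adjusted exact p = 0.405. Neurogenesis factors had 2 of 46, elav (406) and CtBP (36.8), adjusted exact p = 0.0954. Hemocyte and basement membrane genes had none of 24, also with adjusted exact p = 0.0954. Both lists passed at a TSS distance of 1000 bp, with adjusted exact p = 0.0431 and 0.048. Notch pathway genes had 2 of 24, E(spl)m3-HLH (108) and neur (60.3), and synaptic genes had 3 of 38, with Nrx-1 the highest (adjusted exact p = 0.712 and 0.462). Each replicate's own list had none of the 8 Hox genes bound, and 1 each of the dorsoventral, Notch and synaptic genes; Dfd, Antp, ptc, ush and neur were in neither.

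Shares in the remaining lists ran from 8.82% to 22.2%, against 15.5% of all protein-coding genes. Translation factors had 10 of 51 bound, led by eIF6 (1137) and eEF1gamma (240). Proteasome subunits had 6 of 48, with Rpn3 (161) the highest, and oxidative phosphorylation genes 14 of 86, with ND-ASHI (373) the highest. Spliceosomal proteins had 4 of 23 (U2af50, 222), nucleolar ribosome biogenesis 5 of 29 (NHP2, 177), and mitosis 8 of 41 (SMC2, 167). Heat shock proteins and chaperones had 6 of 27 (Hsp27, 472), muscle genes 6 of 40 (Msp300, 273), gut and fat body genes 4 of 24 (Adh, 111), and germline and piRNA genes 3 of 34 (papi, 369). The lowest adjusted p among these 10 lists was 0.493. In the list of replicate 1 the odds ratios of the mitosis, nucleolar, oxidative phosphorylation and gut lists, above 1 in the main list, were 0.922, 0.985, 0.998 and 0.776, and that of oxidative phosphorylation was 0.728 in the list of replicate 2.

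**Figure D4:**
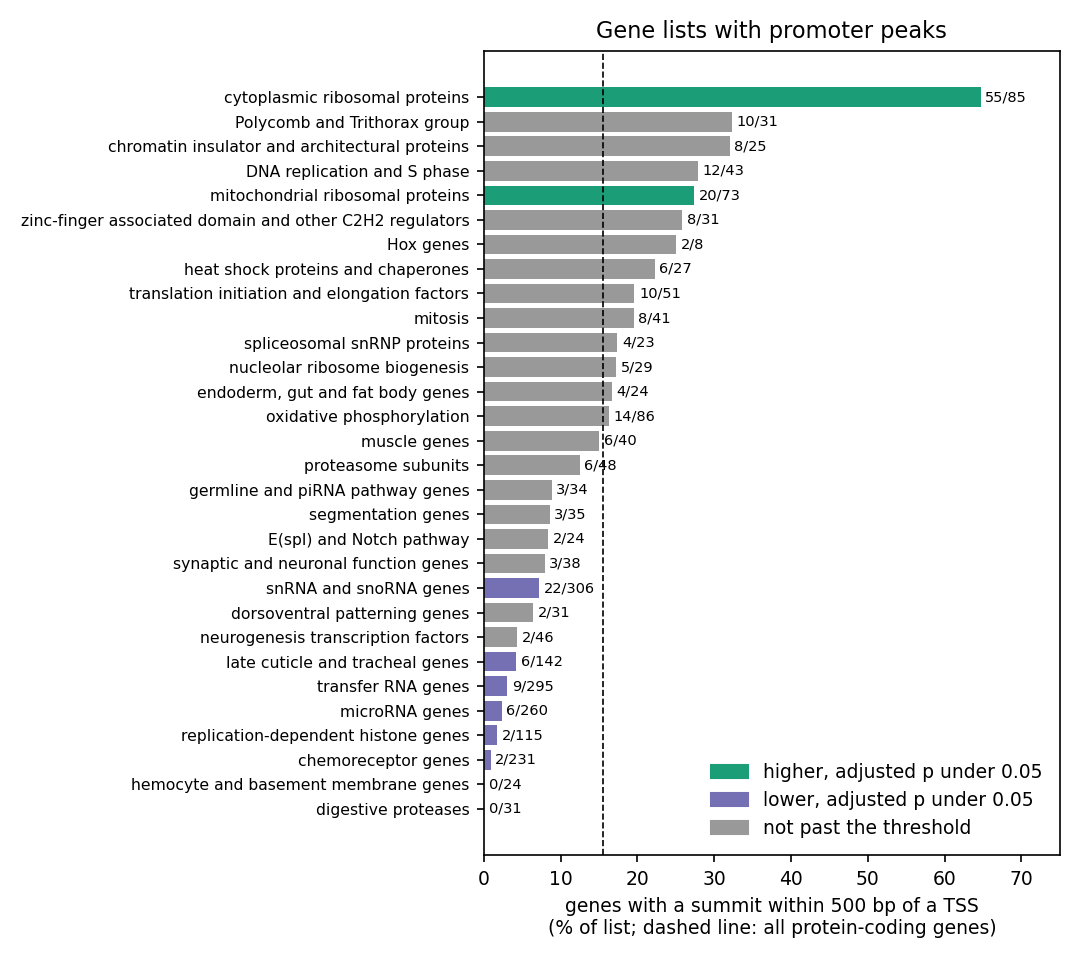
Share of the genes of each list with a peak summit within 500 bp of a TSS (horizontal axis, percent; bound genes over all genes of the list beside each bar), with green and purple bars higher and lower past an adjusted p of 0.05 by two-sided Fisher's exact test, and grey bars not past it. Cytoplasmic ribosomal protein genes stand at 64.7%, against 15.5% of all protein-coding genes (dashed line); digestive proteases, with no bar at 0 of 31, were lower past the threshold, and the RNA gene lists were tested against all genes.

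Of the 31 fixed sequence elements, 7 were found more often within 50 bp of the summits than 300 bp to the side, and 4 less often. The DRE, bound by Dref and BEAF-32, was at 1.44% of summits, 2.62 times its share in the flanks (adjusted exact p = 0.00121, exact sign test with Benjamini-Hochberg adjustment over 31 motifs), and its core ATCGAT at 4.62%, 1.63 times the flanks (adjusted exact p = 0.00277). The other elements that were higher were the TATA box (1.73 times, 19.8% of summits, adjusted exact p = 4.87e-24), the Mef2 site (1.99 times, adjusted exact p = 2.28e-08), Ohler motif 7 (1.66 times, adjusted exact p = 3.15e-06), the homeodomain site (1.41 times, adjusted exact p = 0.000198) and the GATA site (1.27 times, adjusted exact p = 0.0216). The TATA box, Mef2 site, homeodomain site, GATA site and DRE consist mostly of A and T, in which summits were richer than the flanks. Lower were the GAGA element (0.423 times the flanks, adjusted exact p = 5e-07), the Clamp repeat (0.361 times, adjusted exact p = 9e-05, and 0.226 and 0.167 times in the lists of replicate 1 and replicate 2), the CA repeat (0.435 times, adjusted exact p = 5e-07) and the E2F site (0.75 times, adjusted exact p = 0.00807). M1BP's motif (1.12 times) and the Zelda site (0.906 times) did not differ past the threshold. With flanks 500 bp away M1BP's motif was at 2.71 times (adjusted exact p = 0.0349), and it was at 0.8 and 2 times in the lists of replicate 1 and replicate 2, without passing. The Adf1 motif (0.695 times, adjusted exact p = 0.102) did not pass either, but did as lower in the lists of replicate 1 and replicate 2, at 0.502 and 0.526 times (adjusted exact p = 2.47e-05 and 4.03e-05), and among peaks above the median signal, at 0.481 times (adjusted exact p = 0.00381). It also passed in the conservative list, in the ranked list at the same score and with windows of 100 bp to each side, at 0.655, 0.686 and 0.687 times. Ohler motif 6 (1.71 times) passed as higher with those wider windows (1.64 times, adjusted exact p = 0.00123), with flanks 500 bp away (2 times, adjusted exact p = 0.0175) and in the ranked list (1.59 times, adjusted exact p = 0.021), but was at 1.05 times in the list of replicate 1 (adjusted exact p = 0.652). The E-box CACGTG (0.619 times) passed as lower with the wider windows (adjusted exact p = 0.0242) and in the list of replicate 1 (0.463 times, adjusted exact p = 0.00691). The Su(Hw) site (1.90 times) passed as higher with the wider windows (adjusted exact p = 0.0106), and the E-box CAGCTG (0.915 times) as lower among peaks above the median signal (adjusted exact p = 0.0392). Among peaks above the median signal the Zelda site was at 0.452 times (adjusted exact p = 0.118; 0.526 times in the list of replicate 2), and the GAGA element, the CA repeat and the Clamp repeat passed at 0.178, 0.266 and 0.186 times. At summits over 500 bp from a TSS 2 elements were higher, the TATA box and the Mef2 site, and the DRE was at 1.14 times its flank share (adjusted exact p = 1). Among peaks above the median signal the DRE (adjusted exact p = 0.691) and its core (0.931) did not pass; Ohler motif 7 and the DRE core did not in the list of replicate 1 (0.11), the GATA site without summits beside a stronger one (0.094), or the E2F site in the lists of replicate 1 (0.211) and replicate 2 (0.0522).

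Summits were richer in A and T than their surroundings. Windows reaching 50 bp to each side of the summit were 36.8% G and C, against 42.9% in the flanks. Of all 6-mers, with reverse complements merged, 340 were more frequent at summits and 601 less frequent past an adjusted p of 0.05. The 340 include 202 of the 228 6-mers with 5 or 6 A or T bases, led by AAATAT (29.5% of summits against 16.4% of flanks, adjusted exact p = 3.4e-39). AAATAT was at 1.79 times and TTTAAA at 1.99 times its flank share. The higher shares of the TATA box, Mef2 site, homeodomain site, GATA site and DRE are therefore not told apart from base composition. Among the 6-mers that were less frequent, CTCCTC was first by p, at 0.381 times its flank share (adjusted exact p = 1.06e-12). The 601 include 573 of the 1360 6-mers with 3 or more G or C bases, and 1 of the 228 with 5 or 6 A or T bases. The GAGA element, Clamp repeat, CA repeat and E2F site are richer in G and C than the summits. Their lower shares are therefore not told apart from base composition either.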

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

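The motif tests on the absent peaks and the test of low-signal peaks were chosen after the results were seen. The other tests here were chosen before their own outcomes were seen.

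Some of the strongest peaks of the ranked list are absent from the thresholded list, although their scores pass it. Of the 3945 ranked peaks with a score of 830 or more, 130 are absent, and the highest of them has a signal value of 6168, above the 4550 of the strongest peak kept. The 2 absent peaks that exceed every peak kept lie near Rh5, at 2L:12006910-12007849 (6168) and 2L:12004484-12006277 (5674). Further strong ones lie near Hacd1 (2831), lncRNA:CR44588 (3025), ssp3 (2018), COX7AL2 (2015) and cbt (1472). Of the 119 on the 7 chromosomes, 43 lie on 2L and 62 on 3R, and joining those within 10 kb leaves 52 regions. The region with the most peaks is 2L:12002955-12012662, with 13, and it takes in all those near Rh5, Hacd1 and lncRNA:CR44588.

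Sequence present in several copies in the assembly is argued against for most of these peaks, since 4.2% of them have most of their 31-mers more than once there. The share was 0.105% among all peaks of the main list, so such sequence is more common among the absent peaks. Copies that the assembly lacks could not be counted. Of the 119 summits, 84 and 85 pass a score of 830 in the ranked lists of replicate 1 and replicate 2, yet only 0.84% lie inside a thresholded peak of any of the 4 lists. A candidate explanation is therefore that the same fixed regions were removed from each list by the authors, perhaps through the further file behind the thresholded lists, whose content was not analysed here. The motif of the strong distal peaks that were kept was at 20.2% of the absent summits and 3.78% of their flanks (exact sign test p = 1.94e-05). The 38 with signal values as in the 200 strongest distal peaks kept had it in 52.6% (10.5% of flanks), and the other 81 in 4.94% (0.617%). Many of these summits are neighbours, and those 38 lie in 14 regions, where the strongest summit had it in 3 cases. Over all 52 regions the strongest summit had it in 4 cases and its flanks in 0 (exact sign test p = 0.125). With 4 such summits this test could give no smaller p. Whether the absent peaks are binding sites of the kind seen at the kept peaks therefore stays open. With 1 group in the design, no biological explanation that sets groups against each other was tested.

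Peaks of low signal also passed the threshold, 144 of them with a value under 20. Of these, 97.9% lie within 300 bp of a stronger summit, against 1.83% of the peaks of 20 or more, which is consistent with second summits called beside a stronger peak.

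The main list has 5 peaks on unplaced scaffolds, which no comparison used.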

How the results depend on the processing

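Settings added after the data were seen were the ranked list at the same score, the removal of summits beside a stronger one, summits given to 1 gene, other TSS sets for paired promoters, mature microRNA entries, and replicates set against ranked lists. The promoter share, its excess over random positions, the higher signal at promoters, the excess at paired promoters, the 6-mer counts, the number of gene lists bound less often and the replicate overlap kept their direction and their side of the threshold, or stayed within 1.5 times, in every setting run. Gene lists bound more often numbered 2, rising to 3 at a TSS distance of 250 bp or with a single TSS per gene and falling to 1 with the conservative list, the peaks above the median signal, a TSS distance of 1000 bp or summits given to 1 gene; leaving out a replicate gave 1 to 2. Elements more frequent at summits numbered 7, and 2 for summits over 500 bp from a TSS. Chromosomes that differ from prediction numbered 3, and 1 for promoter peaks given their TSSs. The Spearman correlation of signal values between replicates was 0.790, with 0.763 for peaks above the median and 0.759 over all main-list peaks found in both ranked lists. Leaving out a replicate left 2402 to 2602 peaks. Reversed were the small nuclear and nucleolar RNA list at 1000 bp (odds ratio 1.09) and the E2F site away from TSSs, where it was still 0.953 times as frequent as in the flanks, but 79 summits had it alone against 66 flanks in the sign test. The fewer peaks of the smaller lists lower the power by construction; otherwise the cause was not tested. Among single lists, elements and chromosomes, 572 values stayed on their side of the threshold, 24 no longer passed it and 23 came to pass it. Leaving out a replicate uses the other's own list. Depth is unknown and sets no limit that could be computed here.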

Other observations

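The tests of the motif on arms not used in learning and with 1 summit per region, and both tests of neighbouring strong peaks were chosen after the results were seen. The others in this part were chosen before their own outcomes were seen, but the motif itself was learned after the main results.

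A sequence motif was learned from the strongest peaks away from promoters. Learned on 2L, 2R and X its consensus was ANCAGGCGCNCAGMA, and learned independently on 3L and 3R it was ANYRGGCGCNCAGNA. Scored with the matrix from the other arms, 91 of the 200 strongest distal summits (45.5%, exact 95% interval 38.5 to 52.7) had a match within 50 bp, against 8.25% of flanks. With the strongest summit of each of 150 regions, made by joining those within 10 kb, 59 summits (39.3%) had one, against 5% of flanks (exact sign test p = 1.54e-12). The share was 68% of the 50 strongest distal summits (12% of flanks), 48% of the next 50 (9%), 33% of the 100 after those (6%) and 7.71% of those beyond rank 1000 (3.45%). At the 200 strongest promoter summits it was 10.5%, against 3.25% of flanks. Among these the 50 strongest had it in 22% (4% of flanks), the next 50 in 10% (2%) and the 100 after those in 5% (3.5%). Taken from each replicate's own list, the 200 strongest distal summits had it in 47.5% (replicate 1) and 38.5% (replicate 2).

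That strong peaks lie nearer to each other than other peaks of the list is a hypothesis noticed in the 20 strongest and then tested by random draws. Of the 100 strongest with summits at least 300 bp from a stronger one, 31 had another of the 100 within 10 kb, against a median of 4 and a highest of 16 in 1000 random draws of 100 peaks (permutation p = 0.001, the smallest they can give). Among peaks over 10 kb from the 20 strongest, where it had not been noticed, 18 of the 100 strongest had such a neighbour, against a median of 4 and a highest of 15. The largest group, at 2R:13576067-13585151, held 5 of the 100, and groups at mam, Tlk (X:3740801-3742964), CG9331 and beat-Ib had 3 each.

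For the motif at strong distal peaks, chance on the arms used to learn it is excluded by the arms not used (exact sign test p = 7.33e-20). Base composition is argued against by 20 motifs with shuffled positions, the highest of which exceeded its flanks by 5.5 percentage points, against 37.3 for the real one. Of the 91 summits with the motif 0 have most 31-mers more than once (0%, with an upper limit of 3.97%), so they do not lie in sequence repeated in the assembly. Among all main-list peaks the share was 0.105%, so almost none was to be found in any case. This result is therefore no separate support for the motif. The motif may be a sequence that the tagged protein, or a partner recovered with it, prefers at distal sites, which remains a hypothesis because the search and its test used the same 2 libraries and other searches came first. With 1 group in the design, no biological explanation that sets groups against each other was tested.

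A hypothesis that the same motif accounts for most peaks at ribosomal protein gene promoters was not borne out. It was at 6.9% of the 58 summits there (exact 95% interval 1.91 to 16.7), with 2.59% in their flanks (exact sign test p = 0.125). These peaks are weaker than most of the strong distal ones, and distal peaks ranked 501 to 1000 had 11.2%, inside that interval, so that no difference from distal peaks of like signal is shown.

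A hypothesis that better matches are occupied more often was tested on 3L and 3R with the matrix from the other arms. Of 7483 matches there, 7.62% of the 748 with the highest scores lay within 100 bp of a summit. Of the 748 with the lowest scores 0.936% did (two-sided Fisher's exact test against the highest 748, p = 3.23e-11). The 100 best matches held 30 of the 57 such matches among the highest 748. The next 748 by score had 2.27%. All groups of 748 below those, down to the lowest, had between 0.668% and 1.47%, with no steady trend. The higher share was therefore found mainly at the best matches, and no graded rise over all scores is shown. Summits of the main list alone were searched, which lacks some strong peaks of 3R.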
